A study of Mus musculus with 12 samples.

How the data were processed

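Total RNA from mouse liver was extracted with Trizol, and biotin-labelled cRNA was prepared from 6 µg of it by the Affymetrix protocol, per the labels. There were 12 arrays, 3 in each of 4 groups: control and Ire1α null livers, with vehicle or tunicamycin. The deposited values are a linear intensity per probe set. The algorithm that summarised the probes, any scaling and any filter are not given in the sources used here. The trimmed means and quantiles of the arrays differed, so the intensity values were taken as not normalized between arrays. The labels call the samples biological replicates and number them 1 to 3 in each group. No label says that a number links groups, so no pairing was used.

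Of 45101 probe sets 64 controls were left out. Gene symbols came from the platform's annotation: 34945 probe sets had 1 symbol, 932 had several and 9160 had none, and the latter 2 kinds were not used in the gene tests. For 34754 probe sets the symbol was looked up by gene ID in a reference list of genes, which changed 0 of them. Intensities were transformed to log2(value + 16) and quantile normalized with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package for reading. The 30% of probe sets with the lowest mean were left out, and each gene was represented by the probe set with the highest mean over the 12 arrays, which left 14568 genes. The gene Bloc1s1, named in the plan, was not analysed here.

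Group means were fitted with lmFit and tested with eBayes over all 12 arrays (8 residual degrees of freedom), in 5 contrasts: tunicamycin against vehicle in control and in null livers, null against control without stress and with tunicamycin, and the genotype by treatment interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. Called genes are said to rise, fall, or be higher or lower, and for others only values are given. Gene lists, 25 of pathways and 10 of cell type markers, were written before the data were examined, as were the design, the threshold and the rule for named genes. They were tested with camera of limma, two-sided, with the preset correlation of 0.01 and again with a correlation estimated from the data, when at least 5 members were measured, with the Benjamini-Hochberg correction over the lists of a contrast. The erythroid, pancreas and adipose lists were measured and not tested. Members called were counted with p adjusted over all genes and adjusted over the list alone. One further list of 24 kidney markers was written after the leading genes of 1 array had been seen.

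Genes named in the text follow a rule fixed beforehand: Ern1 with its probe sets, a list of anchor genes given whether or not they pass, in each contrast the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (or the 5 smallest p values where fewer than 5 pass), and up to 4 called members of each list, or up to 2 with the smallest p where none is called. Any gene named by 1 part could be used in any contrast, and not all were. The kidney markers fall outside this rule.

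Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter or a 50% filter on dim probe sets, centred array medians, the mean of a gene's probe sets, every probe set on its own, no _x_at and _s_at probe sets, eBayes with trend and robust options, array quality weights, the replicate number as a block, a 2-fold threshold, a fit of only the 2 groups compared, leaving out each array in turn, and the estimated list correlation. Values as deposited without normalization and the Gapdh or the actin 5' to 3' ratio as a covariate were added after the data had been seen. Single values were compared with exact permutation tests. The steps were tested on simulated data: for the control response, with 14568 genes, 56% of 100 genes made to change 2-fold and 93% of 100 made to change 4-fold were called, with 6 false calls. For the interaction, with the same number of genes, 1 of 1 shifted list and 0 of 30 others were called. Simulated genes varied independently and the lists were drawn at random, so list calls for genes that vary together were not checked. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.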

Results

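The study profiled gene expression in control and Ire1α null mouse livers, with and without endoplasmic reticulum (ER) stress. The sample titles read Fe+CRE+ for control and Fe-CRE+ for null livers, so both genotypes are labelled CRE+. Ire1α, encoded by Ern1, is a kinase and RNase of the ER membrane that senses unfolded protein and splices the Xbp1 transcript. The C57Bl/6J mice were 3 months old. They received tunicamycin, which blocks N-linked glycosylation and so leaves unfolded protein in the ER, at 2 µg per g of body weight, or a dextrose vehicle, both by intraperitoneal injection. Livers were taken 8 hours later. Each of the 4 groups held 3 biological replicates, so that 12 Affymetrix arrays of 45101 probe sets were compared, and 14568 genes were tested. Changes are log2 fold changes ± the standard error of the limma fit with 3 arrays per group, and adjusted p values are those of limma with the Benjamini-Hochberg correction. The number of arrays limits the precision of every value.

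The mean deposited intensity of an array, without the 2% highest and lowest values, lay between 228 and 303. The first principal component, 48.6% of the variance, separated the 6 tunicamycin arrays (-47.3 to -21.0) from the 6 vehicle arrays (29.8 to 40.1). On the second, 15.8%, null tunicamycin replicate 2 lay at -65.6 and the other 11 arrays between -0.701 and 18.4. That array carried transcripts of kidney: 16 of 21 measured kidney markers lay more than 1 (log2) above the highest of the other 11 arrays, among them Umod at a log2 value of 13.1 against at most 6.55 and Kap at 12.8 against at most 5.98. The marker list was written after the leading genes of that array had been seen. The ratio of the 5' to the 3' Gapdh control probe sets, which falls with RNA degradation, averaged 0.528 ± 0.220 (SD, n = 3) in control vehicle, 0.556 ± 0.0289 in control tunicamycin, 0.372 ± 0.241 in null vehicle and 0.401 ± 0.0327 in null tunicamycin arrays. Between null and control livers it showed a difference of -0.155 with tunicamycin (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give) and -0.156 without (exact p = 0.5). Between tunicamycin and vehicle arrays it showed 0.0279 in control (exact p = 0.9) and 0.0294 in null livers (exact p = 0.9). The actin ratio averaged 0.757 ± 0.323 (SD, n = 3) in control vehicle, 0.328 ± 0.0533 in control tunicamycin, 0.500 ± 0.179 in null vehicle and 0.309 ± 0.116 in null tunicamycin arrays. Its tunicamycin arrays did not overlap with the vehicle arrays in control livers (difference -0.429, two-sided exact permutation p = 0.1, the smallest possible). The difference was -0.191 in null livers (exact p = 0.2), and between genotypes -0.0190 with tunicamycin (exact p = 0.8) and -0.257 without (exact p = 0.4).

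**Figure D1:**
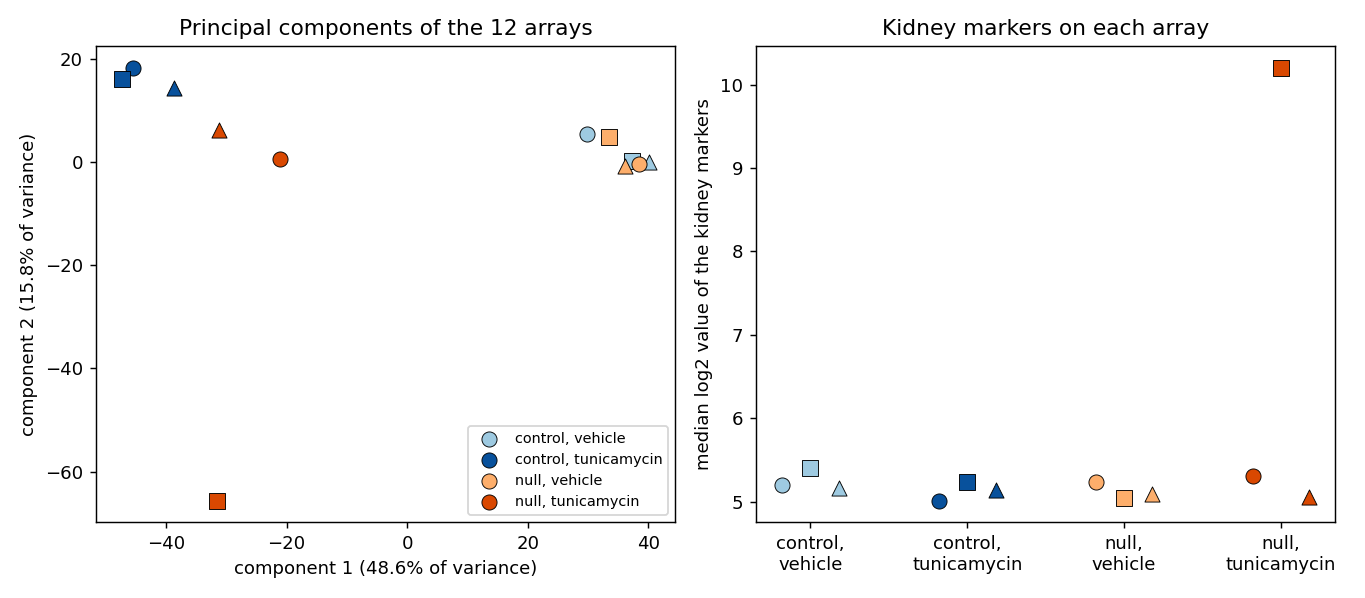
The left panel plots the first against the second principal component of the 12 arrays, and the right panel the median log2 value of 21 kidney markers on each array, with colours for groups and circles, squares and triangles for replicates 1, 2 and 3. Null tunicamycin replicate 2 lies apart in both, with a marker median of 10.2 against 5.02 to 5.41 on the other 11 arrays.

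Ern1, the deleted gene, was read by 5 probe sets. Their changes, standard errors and adjusted p values come from a separate limma fit. It took all 34945 probe sets with 1 symbol, without the filter on dim probe sets. The brightest had a mean deposited intensity of 1436 ± 372 (SD, n = 3) in control vehicle livers and 3387 ± 389 with tunicamycin, and of 1238 ± 219 and 3611 ± 1345 in null livers. It rose with tunicamycin in control livers by 1.03 ± 0.24 (adjusted p = 0.0134) and in null livers by 1.27 ± 0.24 (adjusted p = 0.00731). Null livers differed from control livers by -0.13 ± 0.24 (adjusted p = 0.969) without stress and by 0.10 ± 0.24 (adjusted p = 0.935) with tunicamycin. None of the other 4 Ern1 probe sets passed the limma threshold in a comparison. Their differences between genotypes were -0.23, -0.24, 0.00 and -0.07 without stress, from the brightest to the dimmest, and -0.05, -0.37, 0.05 and -0.16 with tunicamycin. In the same order they changed with tunicamycin by -0.31, -0.66, -0.40 and 0.20 in control livers. In null livers the changes were -0.13, -0.80, -0.35 and 0.11. The called rise thus rests on the brightest probe set alone. The deleted part of Ern1 is not given in the sources used here, so these levels do not show whether a functional transcript was present.

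The tunicamycin response in control livers asks what ER stress does to the liver with Ire1α present. The stress response factors Nupr1 (7.81 ± 0.32), Ddit3, which encodes CHOP (6.01 ± 0.24), and Atf3 (5.45 ± 0.22) rose most, together with the ER degradation gene Derl3 (6.66 ± 0.31), the serine synthesis gene Psat1 (5.30 ± 0.22) and the ER chaperone gene Creld2 (5.05 ± 0.23; largest adjusted p = 9.62e-08). Among the falls were the acyl-CoA thioesterase Acot3 (-4.99 ± 0.43), Nxpe2 (-3.85 ± 0.25), the endothelial lipase Lipg (-3.34 ± 0.22) and the lipogenic transcription factor Srebf1 (-3.22 ± 0.24; largest adjusted p = 9e-06). In all, 1693 genes rose and 1943 fell, 789 and 625 of them at least 2-fold. The 2 groups' arrays did not overlap for 42.6% of genes against 10% by chance. The share of rises depended on the scaling: 2100 rises and 1181 falls with array medians centred, and 2062 and 1068 with values as deposited. The median of all genes was -0.11 after quantile normalization, -0.01 with centred medians and 0.01 as deposited. With the actin ratio as a covariate the count of 3636 fell to 1885, 1030 rises and 855 falls.

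The ER folding machinery rose as a group in control livers. Of 22 ER chaperone and folding genes 21 rose, with a median of 1.87, and 22 rose when adjusted over the list alone (camera adjusted p = 1.04e-21). Examples were Sdf2l1 (3.90 ± 0.17), Pdia4 (3.62 ± 0.25), Hspa5 (1.48 ± 0.19) and Dnajb9 (1.91 ± 0.26), the last 2 encoding BiP and its cochaperone ERdj4 (largest adjusted p = 0.000203). ER-associated degradation genes rose in 16 of 19 cases (16 adjusted over the list alone; median 1.34, adjusted p = 3.15e-15). Examples were Syvn1 (3.87 ± 0.13), Sel1l (2.53 ± 0.13) and Edem1 (1.77 ± 0.15). Of the genes for translocation into and export from the ER, 24 of 30 rose (27 adjusted over the list alone; median 0.96, adjusted p = 2.64e-18). Examples were Srprb (2.80 ± 0.26), Sec24d (1.76 ± 0.15) and Sec61a1 (1.51 ± 0.14). N-glycosylation genes rose in 15 and fell in 1 of 24 cases (16 and 1 adjusted over the list alone; median 0.97, adjusted p = 6.53e-11). Examples were Gmppb (3.84 ± 0.22), Gfpt1 (3.49 ± 0.18) and Dolpp1 (1.75 ± 0.18) (largest adjusted p = 2.95e-05 for the 9 genes). Targets of ATF4 and CHOP, the PERK branch, rose in 16 of 20 cases (16 adjusted over the list alone; median 2.36, adjusted p = 7.23e-17). Examples were Fgf21 (4.98 ± 0.41), Trib3 (4.29 ± 0.21) and Atf4 (2.11 ± 0.14). Aminoacyl-tRNA synthetases rose in 12 and fell in 1 of 16 cases (14 and 1 adjusted over the list alone; median 1.02, adjusted p = 3.15e-10). Examples were Wars (2.91 ± 0.17), Iars (1.66 ± 0.14) and Gars (1.46 ± 0.13) (largest adjusted p = 1.23e-05 for the 6 genes). These 6 lists kept their calls (largest adjusted p = 0.035 with an estimated correlation). The Xbp1 transcript, spliced or not, rose by 0.55 ± 0.14 (adjusted p = 0.011). That Xbp1 call was lost with the mean of its probe sets (0.42, adjusted p = 0.114), without _x_at and _s_at probe sets (0.63, adjusted p = 0.33) and with the actin ratio as a covariate (0.35, adjusted p = 0.212).

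A further 4 lists passed in control livers with negative medians at the preset correlation, and none of them with an estimated one. Cholesterol synthesis genes fell in 9 and rose in 1 of 19 cases (11 and 1 adjusted over the list alone; median -0.77, adjusted p = 0.00872, adjusted p = 0.437 with an estimated correlation). Idi1 (-2.09 ± 0.30), Dhcr7 (-2.09 ± 0.26) and Msmo1 (-1.66 ± 0.21) were among the falls, and Mvd (1.85 ± 0.23) rose. Of 10 periportal genes 5 fell (6 adjusted over the list alone; median -0.43, adjusted p = 0.00698, adjusted p = 0.0702 with an estimated correlation). Examples were Hal (-2.36 ± 0.22) and Aldh1b1 (-1.98 ± 0.21). Fatty acid oxidation genes fell in 7 and rose in 1 of 18 cases (9 and 1 adjusted over the list alone; median -0.39, adjusted p = 0.0146, adjusted p = 0.437 with an estimated correlation). Ppargc1a fell by 1.91 ± 0.49 and Pdk4 rose by 1.67 ± 0.32 (largest adjusted p = 0.014 for these 8 genes). Ppargc1a lost its call with the actin ratio as a covariate (-2.22, adjusted p = 0.0571). Complement and coagulation genes fell in 7 of 23 cases (8 adjusted over the list alone; median -0.34, adjusted p = 0.0226, adjusted p = 0.673 with an estimated correlation). The complement call was lost without control vehicle replicate 1 (median -0.32, adjusted p = 0.0656). Complement genes also lost it with centred medians (median -0.19, adjusted p = 0.134) and with values as deposited (median -0.16, adjusted p = 0.166). The fatty acid call was lost with centred medians (median -0.25, adjusted p = 0.0789) and with values as deposited (median -0.23, adjusted p = 0.086). Alb (0.03 ± 0.12, adjusted p = 0.895), Apob (-0.22 ± 0.47, adjusted p = 0.784) and Cyp7a1 (-0.37 ± 0.26, adjusted p = 0.334) did not pass. A call was kept with a median moved more than 1.5-fold for periportal (to -0.28 with values as deposited, adjusted p = 0.0194).

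Other lists did not pass in control livers, although single members did. Liver transcription factors came closest, with 1 rise and 5 falls of 16 (1 and 5 adjusted over the list alone; median -0.40, adjusted p = 0.0556). The falls included Nr1i3 (-2.83 ± 0.27), Foxa2 (-1.88 ± 0.32) and Cebpa (-1.44 ± 0.29) (largest adjusted p = 0.00325). Transcripts reported as substrates of the IRE1 RNase fell in 4 of 13 cases (5 adjusted over the list alone; median -0.39, adjusted p = 0.0617), for example Ces1g (-1.99 ± 0.28, adjusted p = 0.000278). The lipid lists were lipogenesis (1 rose and 6 fell of 19, 1 and 6 adjusted over the list alone, median -0.34, adjusted p = 0.0821), lipoprotein (0 rose and 5 fell of 18, 0 and 5 adjusted over the list alone, median -0.14, adjusted p = 0.129) and lipid droplet (4 rose and 1 fell of 14, 4 and 2 adjusted over the list alone, median 0.05, adjusted p = 0.33). Liver function lists were cytochrome P450 (1 rose and 5 fell of 19, 1 and 5 adjusted over the list alone, median -0.28, adjusted p = 0.113), bile acid (1 rose and 4 fell of 16, 2 and 4 adjusted over the list alone, median -0.23, adjusted p = 0.466), glucose metabolism (3 rose and 4 fell of 14, 3 and 5 adjusted over the list alone, median -0.32, adjusted p = 0.579), pericentral (1 rose and 1 fell of 11, 1 and 1 adjusted over the list alone, median -0.15, adjusted p = 0.476) and acute phase (2 rose and 2 fell of 24, 2 and 2 adjusted over the list alone, median 0.00, adjusted p = 0.735). Stress and growth lists were p53 and cell death (6 rose and 3 fell of 13, 6 and 3 adjusted over the list alone, median 0.11, adjusted p = 0.191), immediate-early (2 rose and 3 fell of 12, 2 and 3 adjusted over the list alone, median 0.14, adjusted p = 0.627), NRF2 target (1 rose and 4 fell of 12, 1 and 4 adjusted over the list alone, median -0.10, adjusted p = 0.476), circadian clock (3 rose and 4 fell of 15, 4 and 4 adjusted over the list alone, median -0.20, adjusted p = 0.962) and proliferation (1 rose and 0 fell of 14, 0 and 0 adjusted over the list alone, median -0.10, adjusted p = 0.878). Their called members included Cdkn1a (4.65 ± 0.38), Gadd45a (2.57 ± 0.44), Myc (2.42 ± 0.28), Nfil3 (2.22 ± 0.20), Arntl (3.21 ± 0.26) and Srxn1 (1.61 ± 0.16) (largest adjusted p = 0.0011). Cell type markers gave medians of hepatocyte (0.01, adjusted p = 0.735), Kupffer cell and macrophage (-0.48, adjusted p = 0.371), neutrophil and monocyte (-0.26, adjusted p = 0.82), lymphocyte (-0.27, adjusted p = 0.244), endothelial (-0.08, adjusted p = 0.899), stellate cell and fibroblast (-0.20, adjusted p = 0.605) and bile duct cell (-0.19, adjusted p = 0.863). Of the lists too short for a test, 2 of 3 erythroid markers fell (median -0.82), and neither the 4 pancreas (median -0.14) nor the 3 adipose markers (median -0.28) held a call. Median, mean and test differed in sign for the acute phase, circadian clock and proliferation lists.

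The tunicamycin response in Ire1α null livers asks which part of the stress response remains without the kinase. The genes that rose most were again Nupr1 (7.03 ± 0.32), Derl3 (5.66 ± 0.31), Atf3 (5.54 ± 0.22), Ddit3 (5.37 ± 0.24), Creld2 (4.78 ± 0.23) and Psat1 (4.63 ± 0.22; largest adjusted p = 6.97e-07). Among the falls were Nxpe2 (-4.14 ± 0.25), Lipg (-3.83 ± 0.22), Acot3 (-3.80 ± 0.43) and Srebf1 (-2.69 ± 0.24; largest adjusted p = 0.000138). In total 1105 genes rose and 1344 fell, 457 and 425 of them at least 2-fold. The groups' arrays were separated for 33.1% of genes (10% by chance). Centred medians gave 1256 rises and 703 falls, and values as deposited 1477 and 512. The median of all genes here was -0.07 after quantile normalization, 0.01 centred and 0.08 as deposited. The count of 2449 fell to 1617 without null tunicamycin replicate 3 and 1614 without null vehicle replicate 1, and was 2186 without the array with kidney transcripts. Of these 2186 genes, 1856 were among the 2449. With the actin ratio as a covariate the count was 1651.

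ER chaperone genes rose in null livers as well, in 18 of 22 cases (18 adjusted over the list alone; median 1.31, camera adjusted p = 1.19e-21). Examples were Sdf2l1 (3.82 ± 0.17), Pdia4 (3.35 ± 0.25), Hspa5 (1.83 ± 0.19) and Dnajb9 (1.49 ± 0.26) (largest adjusted p = 0.00212). ATF4 and CHOP targets rose in 17 of 20 cases (17 adjusted over the list alone; median 2.26, adjusted p = 2.16e-20). Examples were Fgf21 (4.61 ± 0.41), Trib3 (3.93 ± 0.21) and Atf4 (2.05 ± 0.14). Of the synthetases, 13 of 16 rose (13 adjusted over the list alone; median 0.98, adjusted p = 9.63e-12). Examples were Wars (2.12 ± 0.17), Iars (1.57 ± 0.14) and Gars (1.54 ± 0.13) (largest adjusted p = 2.52e-05 for the 6 genes). ER-associated degradation genes rose in 11 of 19 cases (13 adjusted over the list alone; median 0.54, adjusted p = 1.1e-08). Examples were Syvn1 (2.87 ± 0.13), Sel1l (2.05 ± 0.13) and Edem1 (1.26 ± 0.15) (largest adjusted p = 0.000167). These 4 lists kept their calls (largest adjusted p = 0.0321 with an estimated correlation). Xbp1 rose by 1.21 ± 0.14 (adjusted p = 0.000133).

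Translocation and export genes rose in 8 and fell in 1 of 30 cases in null livers (9 and 1 adjusted over the list alone; median 0.24, adjusted p = 0.00549, adjusted p = 0.6 with an estimated correlation). That call was lost without null tunicamycin replicate 2 (median 0.12, adjusted p = 0.0855). Sec11a rose by 1.23 ± 0.11 (adjusted p = 3.04e-05). Srprb rose by 0.94 ± 0.26 (adjusted p = 0.0304), a call lost without any 1 of null tunicamycin replicate 2 and null vehicle replicates 1, 2 and 3 (0.63 to 0.96, adjusted p = 0.0624 to 0.0897), and with the mean of its probe sets (0.52, adjusted p = 0.131) and with the Gapdh ratio as a covariate (0.90, adjusted p = 0.0518). For Sec61a1 (0.45 ± 0.14, adjusted p = 0.0455) the call was lost without any 1 array except null tunicamycin replicate 1 (0.36 to 0.51, adjusted p = 0.0524 to 0.144), and with a pseudocount of 1 (0.46, adjusted p = 0.0558), without the filter on dim probe sets (0.45, adjusted p = 0.0559), with the mean of its probe sets (0.41, adjusted p = 0.202), with the replicate number as a block (0.45, adjusted p = 0.065), with the Gapdh ratio as a covariate (0.44, adjusted p = 0.0632) and with the actin ratio as a covariate (0.48, adjusted p = 0.0877). N-glycosylation genes rose in 5 and fell in 1 of 24 cases (6 and 1 adjusted over the list alone; median 0.25, adjusted p = 0.0018, adjusted p = 0.138 with an estimated correlation). Examples were Gfpt1 (2.26 ± 0.18) and Gmppb (1.55 ± 0.22) (largest adjusted p = 0.000627). Both lists kept their calls with medians moved more than 1.5-fold here: ER translocation and export (to 0.41 with centred medians, adjusted p = 0.000112, 0.48 with values as deposited, adjusted p = 6.24e-05 and 0.13 without null vehicle replicate 1, adjusted p = 0.0133), and N-glycosylation (to 0.42 with centred medians, adjusted p = 0.000127, 0.50 with values as deposited, adjusted p = 0.000185 and 0.16 without null vehicle replicate 1, adjusted p = 0.00539).

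A further 6 lists passed in null livers at the preset correlation and not with an estimated one. The p53 and cell death list held 5 rises and 1 fall of 13 (median 0.58, adjusted p = 0.0273, adjusted p = 0.342 with an estimated correlation). The p53 call was lost without either null tunicamycin replicate 2 or null vehicle replicate 2 (median 0.13 to 0.42, adjusted p = 0.0873 to 0.0929). Without the first of these, the array with kidney transcripts, the p53 median was 0.13. Immediate-early genes rose in 5 of 12 cases (median 0.71, adjusted p = 0.00822, adjusted p = 0.217 with an estimated correlation). Called members of these 2 lists included Gadd45a (4.48 ± 0.44), Cdkn1a (3.60 ± 0.38), Myc (3.38 ± 0.28) and Jun (1.65 ± 0.27) (largest adjusted p = 0.00159). Cholesterol synthesis genes fell in 7 and rose in 1 of 19 cases (median -0.36, adjusted p = 0.0176, adjusted p = 0.6 with an estimated correlation). The cholesterol call was lost without either null tunicamycin replicate 2 or null vehicle replicate 3 (median -0.31, adjusted p = 0.0776 to 0.118). Idi1 (-1.93 ± 0.30), Msmo1 (-1.58 ± 0.21) and Dhcr7 (-1.56 ± 0.26) fell (largest adjusted p = 0.00163). Complement and coagulation genes fell in 8 of 23 cases (median -0.42, adjusted p = 0.000611, adjusted p = 0.6 with an estimated correlation). Periportal genes fell in 4 of 10 cases (median -0.37, adjusted p = 0.0176, adjusted p = 0.143 with an estimated correlation). Examples were Aldh1b1 (-1.64 ± 0.21) and Hal (-1.48 ± 0.22) (largest adjusted p = 0.000852). Kupffer cell and macrophage markers had a median of -0.52 (2 of 12 fell, adjusted p = 0.0408, adjusted p = 0.641 with an estimated correlation). The Kupffer call was lost without any 1 of null tunicamycin replicates 1 and 2 and null vehicle replicate 2 (median -0.52 to -0.29, adjusted p = 0.162 to 0.276). Kupffer markers also lost it with the replicate number as a block (median -0.52, adjusted p = 0.0507). Counts adjusted over the list alone were 6 higher and 1 lower for the p53 list, 7 and 2 for immediate-early genes, 1 and 8 for cholesterol synthesis, 0 and 10 for complement, 0 and 5 for periportal genes and 0 and 2 for Kupffer markers. Bile duct cell markers had a median of 1.38 with and 0.05 without the array with kidney transcripts, and did not pass (adjusted p = 0.194). The other lists did not pass (adjusted p = 0.0678 to 0.961), and the circadian clock list's median, mean and test differed in sign. Calls were kept with medians moved more than 1.5-fold for complement and coagulation (to -0.26 without null tunicamycin replicate 2, adjusted p = 0.0251), cholesterol synthesis (to -0.22 with centred medians, adjusted p = 0.0302, -0.15 with values as deposited, adjusted p = 0.0168 and -0.57 without null tunicamycin replicate 3, adjusted p = 0.00302), and Kupffer cell and macrophage (to -0.31 with values as deposited, adjusted p = 0.0312 and -0.86 with the actin ratio as a covariate, adjusted p = 7.16e-05).

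The response of null livers resembled that of control livers, with a Pearson r of 0.774 and a Spearman rho of 0.709 across the 14568 genes, which are not independent replicates. Without null tunicamycin replicate 1, 2 or 3, r was 0.730, 0.807 or 0.698. Of the 3636 genes called in control livers 3477 (95.6%) moved the same way in null livers. Calls were shared for 870 rises, where independent lists would share 128, and for 1021 falls, where they would share 179, and 5 genes were called in opposite directions. The pair of contrasts shares no array. Genes that rose in control livers kept a median of 92.2% of that rise in null livers among 16 ATF4 and CHOP targets, 90.6% among 12 aminoacyl-tRNA synthetases, 89.7% among 21 chaperone genes, 63.3% among 16 ER-associated degradation genes, 40.3% among 15 N-glycosylation genes and 24.8% among 24 translocation and export genes. These genes were picked for their rise in control livers, a choice that by itself tends to lower the share kept. The shares include the array with kidney transcripts and were not computed without it. Over all members, picked or not, the medians in control and null livers were 2.36 and 2.26 for ATF4 and CHOP targets, 1.02 and 0.98 for synthetases, 1.87 and 1.31 for chaperone genes, 1.34 and 0.54 for ER-associated degradation, 0.97 and 0.25 for N-glycosylation and 0.96 and 0.24 for translocation and export genes. By these medians the null response was smaller than by the shares kept for chaperone, ER-associated degradation and N-glycosylation genes.

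**Figure D2:**
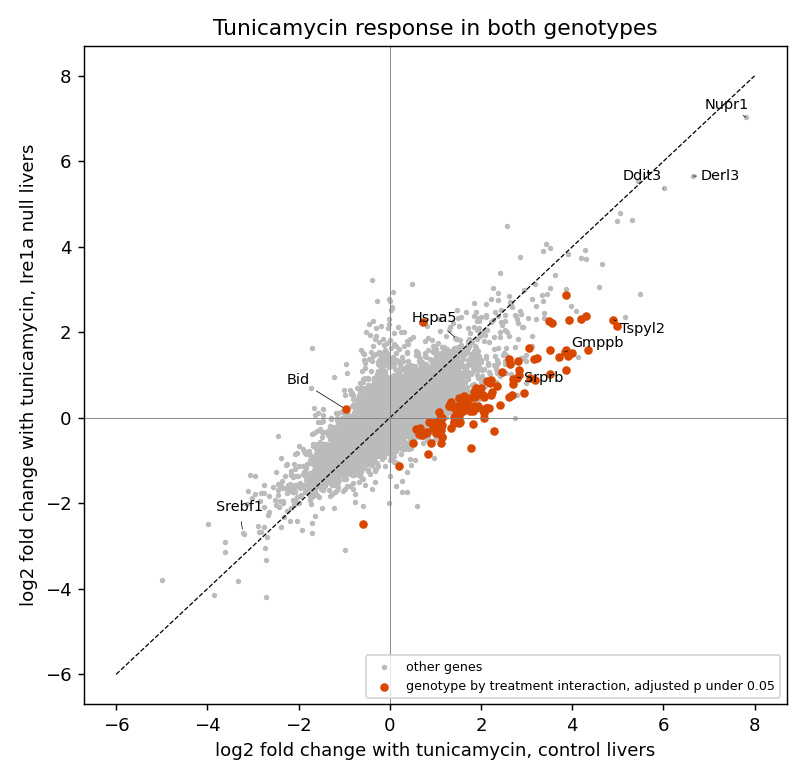
Each point is a gene, with its log2 fold change after tunicamycin in control livers on the horizontal and in Ire1α null livers on the vertical axis, and the dashed line marks equal changes. The 122 genes called in the genotype by treatment interaction are coloured, and 120 of them lie below the line.

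Ire1α null livers were set against control livers without stress to ask what the deletion does at rest. No gene passed (0 of 14568 with limma, smallest adjusted p = 0.973). An unadjusted p under 0.05 was found for 597 where chance gives 728, and 8.15% of genes were separated between the groups (10% by chance). The spread was pooled over all arrays, so tunicamycin arrays also bear on the 597. Without null tunicamycin replicate 2, the array with kidney transcripts, it was 777. Leaving out single arrays gave 389 (without null vehicle replicate 1) to 1116 (without control vehicle replicate 2). The 597 thus does not show that the genotypes differed less than chance gives. The smallest p values, none past the threshold, belonged to C730036E19Rik (1.26 ± 0.21), Phf6 (0.97 ± 0.18), Zfp40 (0.98 ± 0.20), Susd4 (1.09 ± 0.23) and Ctse (-3.03 ± 0.64; largest adjusted p = 0.988). Stress genes were not called, among them Hspa5 (-0.28 ± 0.19), Dnajb9 (-0.61 ± 0.26), Sec61a1 (-0.16 ± 0.14), Xbp1 (-0.10 ± 0.14) and Ddit3 (0.61 ± 0.24; largest adjusted p = 0.988). Metabolic genes gave Srebf1 (-0.23 ± 0.24), Apob (0.03 ± 0.47), Mttp (0.02 ± 0.19), Cyp7a1 (0.15 ± 0.26) and Alb (0.08 ± 0.12; largest adjusted p = 0.998).

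Small shared shifts of gene lists passed camera with the preset correlation and none did with an estimated one. The cholesterol synthesis list had a median of -0.58 over 19 genes (adjusted p = 1.24e-12, adjusted p = 0.139 with an estimated correlation), 8 of them lower when adjusted over the list alone and 0 over all genes, including Mvk (-0.88 ± 0.19) and Pmvk (-0.76 ± 0.20). Without null vehicle replicate 2 the median was -0.34 (adjusted p = 4.72e-07). ATF4 and CHOP targets passed with a positive median (0.19, adjusted p = 0.0127, adjusted p = 0.238 with an estimated correlation; 1 adjusted over the list alone), and this call was lost without null vehicle replicate 1 (median 0.06, adjusted p = 0.135). Asns (1.96 ± 0.50) and Ddit4 (1.15 ± 0.37) were not called. ER chaperone genes had a median of -0.21 (adjusted p = 0.000381, adjusted p = 0.212 with an estimated correlation). The chaperone call was lost with the Gapdh ratio as a covariate (median -0.08, adjusted p = 0.109). Translocation genes had a median of -0.11 (adjusted p = 0.000351, adjusted p = 0.503 with an estimated correlation). N-glycosylation genes had a median of -0.13 (adjusted p = 0.00706, adjusted p = 0.212 with an estimated correlation). The N-glycosylation call was lost without control vehicle replicate 1 (median -0.13, adjusted p = 0.0912). N-glycosylation genes also lost it with the Gapdh ratio as a covariate (median -0.09, adjusted p = 0.0606). Lipogenesis genes had a median of -0.23 (adjusted p = 0.0278, adjusted p = 0.512 with an estimated correlation). The lipogenesis call was lost without any 1 of null tunicamycin replicate 2, control vehicle replicates 1, 2 and 3 and null vehicle replicate 3 (median -0.27 to -0.13, adjusted p = 0.0583 to 0.539). Lipogenesis genes also lost it with the Gapdh ratio as a covariate (median -0.23, adjusted p = 0.078). Among cell type lists, neutrophil and monocyte markers had a median of -0.51 (adjusted p = 0.00706, adjusted p = 0.184 with an estimated correlation). The neutrophil call was lost without control vehicle replicate 1 (median -0.41, adjusted p = 0.0658). Neutrophil markers also lost it without the filter on dim probe sets (median -0.06, adjusted p = 0.468) and with the Gapdh ratio as a covariate (median -0.44, adjusted p = 0.078). For Kupffer cell and macrophage markers the median was -0.41 (adjusted p = 0.00245, adjusted p = 0.512 with an estimated correlation). The Kupffer call was lost without either control vehicle replicate 1 or null vehicle replicate 3 (median -0.30 to -0.20, adjusted p = 0.142 to 0.154). Kupffer markers also lost it with the Gapdh ratio as a covariate (median -0.20, adjusted p = 0.155). Lymphocyte markers had a median of -0.20 (adjusted p = 0.0287, adjusted p = 0.212 with an estimated correlation). The lymphocyte call was lost without any 1 of control vehicle replicates 1 and 3 and null vehicle replicate 1 (median -0.22 to -0.16, adjusted p = 0.0707 to 0.227). Lymphocyte markers also lost it without the filter on dim probe sets (median -0.19, adjusted p = 0.0506) and with the Gapdh ratio as a covariate (median -0.14, adjusted p = 0.155). Adjusted over the list alone, no member of the chaperone (0), translocation (0), N-glycosylation (0), lipogenesis (0) or these 3 cell type lists (0, 0 and 0) was lower. The other lists did not pass (adjusted p = 0.0637 to 0.974), and median, mean and test differed in sign for the lipoprotein, bile acid, complement and coagulation, circadian clock and hepatocyte lists. Medians moved more than 1.5-fold with the call kept for ATF4 and CHOP (to 0.08 with the Gapdh ratio as a covariate, adjusted p = 0.0474 and 0.09 without control vehicle replicate 3, adjusted p = 0.0408), ER chaperone and folding (to -0.33 with the actin ratio as a covariate, adjusted p = 9.89e-06 and -0.11 without null vehicle replicate 1, adjusted p = 0.0122), ER translocation and export (to -0.05 with the actin ratio as a covariate, adjusted p = 0.00464), N-glycosylation (to -0.20 with the actin ratio as a covariate, adjusted p = 0.0025), Kupffer cell and macrophage (to -0.72 with the actin ratio as a covariate, adjusted p = 1.16e-08), and lymphocyte (to -0.31 without control vehicle replicate 2, adjusted p = 0.0169).

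**Figure D3:**
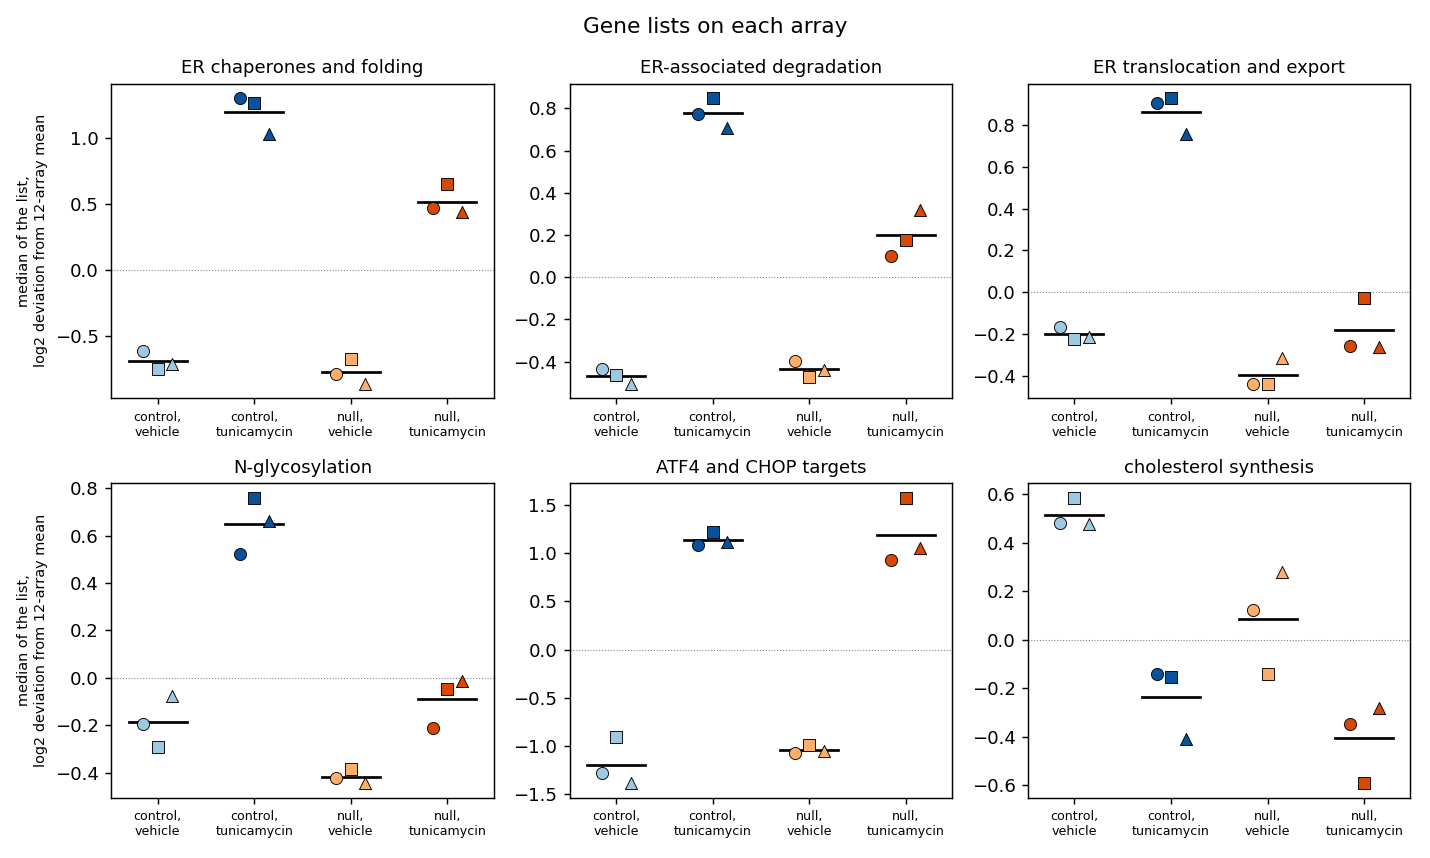
Each panel shows the median of a gene list on each array, as the log2 deviation from the mean of the 12 arrays, with lines at the group means and symbols for replicates. With tunicamycin the translocation and export list was lower in null than in control livers (median -1.07), while the ATF4 and CHOP list differed by a median of 0.05. The ATF4 and CHOP list read 1.57 on null tunicamycin replicate 2, the array with kidney transcripts, and 0.93 and 1.06 on its mates.

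Ire1α null livers were compared with control livers under tunicamycin to find the genes whose level under stress depends on the kinase. The transcription factor gene Bhlha15 (-3.06 ± 0.37), Zfp9 (-2.91 ± 0.20), Nde1 (-2.88 ± 0.21), Tspyl2 (-2.72 ± 0.15) and Ccdc149 (-2.73 ± 0.26) were lower in null livers, as were the mannose donor enzyme gene Gmppb (-2.38 ± 0.22) and the signal recognition particle receptor gene Srprb (-1.98 ± 0.26; largest adjusted p = 0.00126). Higher in null livers were the adenylate kinase gene Ak4 (1.57 ± 0.26), the clock output factor Hlf (1.36 ± 0.20), Bid (1.01 ± 0.14) and the bile acid receptor gene Nr1h4 (0.87 ± 0.15; largest adjusted p = 0.00714). Bid lost its call with the mean of its probe sets (0.56, adjusted p = 0.0969). Wee1 (1.69 ± 0.32, adjusted p = 0.0101) and Nr1i3 (1.41 ± 0.27, adjusted p = 0.0118) were higher as well, calls that were lost without control tunicamycin replicate 2 (adjusted p = 0.0637 and 0.0705). In total 471 genes were lower and 110 higher, 253 and 40 at least 2-fold, and 21.8% of genes were separated (10% by chance). The count of 581 fell to 279 without control tunicamycin replicate 2, 347 without control tunicamycin replicate 1 and 348 without null tunicamycin replicate 1, and was 527 without the array with kidney transcripts. Of these 527 genes, 412 were among the 581. With array quality weights 488 were higher and 796 lower.

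The lists for protein entry into the ER and for glycosylation were lower. Of 30 translocation and export genes 23 were lower (27 adjusted over the list alone; median -1.07, camera adjusted p = 7.38e-36, adjusted p = 0.00924 with an estimated correlation). Examples were Sec61b (-1.51 ± 0.18), Ssr2 (-1.52 ± 0.26) and Sec61a1 (-1.21 ± 0.14). N-glycosylation genes were lower in 12 of 24 cases (16 adjusted over the list alone; median -0.85, adjusted p = 3.02e-18, adjusted p = 0.00152 with an estimated correlation). Examples were Dolpp1 (-1.72 ± 0.18), Ostc (-1.64 ± 0.23) and Dpagt1 (-1.31 ± 0.21). ER-associated degradation genes were lower in 8 of 19 cases (12 adjusted over the list alone; median -0.49, adjusted p = 6.21e-11, adjusted p = 0.00152 with an estimated correlation). Examples were Edem2 (-1.69 ± 0.18) and Syvn1 (-0.87 ± 0.13). ER chaperone genes were lower in 5 of 22 cases (9 adjusted over the list alone; median -0.34, adjusted p = 2.59e-07, adjusted p = 0.0693 with an estimated correlation). Examples were Txndc5 (-1.76 ± 0.20) and Dnajc10 (-1.48 ± 0.19) (largest adjusted p = 0.00558 for the 10 genes). Dnajb9 was lower (-1.04 ± 0.26, adjusted p = 0.0448), a call lost without any 1 array except null tunicamycin replicate 2 and null vehicle replicate 3 (-1.07 to -0.82, adjusted p = 0.0501 to 0.153), and with a pseudocount of 1 (-1.04, adjusted p = 0.0627), without the filter on dim probe sets (-1.04, adjusted p = 0.0542), with the replicate number as a block (-1.04, adjusted p = 0.08) and with the Gapdh ratio as a covariate (-1.03, adjusted p = 0.0874). Edem1 was lower as well (-0.72 ± 0.15, adjusted p = 0.0169), a call lost without any 1 of control tunicamycin replicates 1 and 2 and null tunicamycin replicate 1 (-0.74 to -0.65, adjusted p = 0.0602 to 0.0783). Other stress genes were not called, among them Hspa5 (0.07 ± 0.19), Pdia4 (-0.22 ± 0.25), Ddit3 (-0.03 ± 0.24), Trib3 (0.17 ± 0.21) and Atf4 (-0.35 ± 0.14) (smallest adjusted p = 0.24). The ATF4 and CHOP list had a median of 0.05 with 2 genes higher and 1 lower of 20 (adjusted p = 0.907), and the aminoacyl-tRNA synthetases one of -0.09 (adjusted p = 0.389).

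The Xbp1 transcript was higher in null livers with tunicamycin (0.56 ± 0.14, adjusted p = 0.0434). Its call was lost without any 1 array except control vehicle replicate 1 and null vehicle replicates 2 and 3 (0.53 to 0.61, adjusted p = 0.0538 to 0.153). It was also lost with a pseudocount of 1 (0.56, adjusted p = 0.0594), without the filter on dim probe sets (0.56, adjusted p = 0.0533), with centred medians (0.44, adjusted p = 0.174), with values as deposited (0.48, adjusted p = 0.206), with the mean of its probe sets (0.59, adjusted p = 0.108), without _x_at and _s_at probe sets (0.95, adjusted p = 0.321) and with the replicate number as a block (0.56, adjusted p = 0.0856). Vldlr was higher (1.42 ± 0.34, adjusted p = 0.0366), a call lost without any 1 array except null tunicamycin replicate 3, control vehicle replicates 1 and 3 and null vehicle replicates 1 and 3 (1.27 to 1.54, adjusted p = 0.0526 to 0.122), and with a pseudocount of 1 (1.45, adjusted p = 0.0569), with the mean of its probe sets (0.79, adjusted p = 0.26), without _x_at and _s_at probe sets (1.09, adjusted p = 0.255) and with the Gapdh ratio as a covariate (1.47, adjusted p = 0.0622). Cholesterol synthesis genes had a median of -0.27 with 1 lower of 19 (4 adjusted over the list alone, adjusted p = 0.00181, adjusted p = 0.355 with an estimated correlation). The lower gene was Mvd (-1.72 ± 0.23, adjusted p = 0.00149), and the list's call was lost without null tunicamycin replicate 2 (median -0.33, adjusted p = 0.0615). Immediate-early genes had a median of 0.59 (adjusted p = 0.0148, adjusted p = 0.293 with an estimated correlation). The immediate-early call was lost without null tunicamycin replicate 1 (median 0.44, adjusted p = 0.0531). Immediate-early genes also lost it with the Gapdh ratio as a covariate (median 0.33, adjusted p = 0.0881). NRF2 targets had a median of 0.37 (adjusted p = 0.00255, adjusted p = 0.0879 with an estimated correlation). The NRF2 call was lost without null tunicamycin replicate 2 (median 0.22, adjusted p = 0.0615). For fatty acid oxidation genes the median was 0.25 (adjusted p = 0.00198, adjusted p = 0.293 with an estimated correlation). The fatty acid call was lost without null tunicamycin replicate 1 (median 0.18, adjusted p = 0.0531). Liver transcription factors were higher in 2 of 16 cases (median 0.27, adjusted p = 0.0336, adjusted p = 0.591 with an estimated correlation). The transcription factor call was lost without either null tunicamycin replicate 1 or 3 (median 0.14 to 0.26, adjusted p = 0.105 to 0.444). Transcription factor genes also lost it with centred medians (median 0.15, adjusted p = 0.0763), with values as deposited (median 0.19, adjusted p = 0.104) and with the actin ratio as a covariate (median 0.26, adjusted p = 0.0727). Kupffer cell and macrophage markers had a median of -0.65 (adjusted p = 0.000897, adjusted p = 0.411 with an estimated correlation). The Kupffer call was lost without null tunicamycin replicate 1 (median -0.43, adjusted p = 0.0531). Higher calls adjusted over the list alone were 4 for immediate-early genes, 3 for NRF2 targets, 0 for fatty acid oxidation and 2 for liver transcription factors, and 0 Kupffer markers were lower. The other lists did not pass (adjusted p = 0.118 to 0.937), and median, mean and test differed in sign for the bile acid and lymphocyte lists. With the call kept, medians moved more than 1.5-fold for cholesterol synthesis (to -0.46 with the Gapdh ratio as a covariate, adjusted p = 8.39e-05 and -0.43 without control tunicamycin replicate 3, adjusted p = 0.00039), fatty acid oxidation (to 0.14 with centred medians, adjusted p = 0.0422), liver transcription factor (to 0.48 without null tunicamycin replicate 2, adjusted p = 0.000212), and immediate-early (to 0.34 without null tunicamycin replicate 2, adjusted p = 0.0219). Of the 471 genes lower in null livers 405 (86.0%) had risen with tunicamycin in control livers, where independent lists would share 54.7. Of the 110 higher genes 73 (66.4%) had fallen there, against 14.7. The contrasts share the control tunicamycin arrays, so part of these overlaps may come from them. Simulated data with no change called a mean of only 0.04 lower genes, 0.02 of them raised in control livers, which is too few to bear on the shares. They gave a covariance of the log2 fold changes of -0.0351, against -0.138 in the data, and a correlation of -0.499 against -0.485. The simulated correlation follows from the shared arrays, and the simulated data held no tunicamycin response. These values thus do not tell which part of the overlaps comes from the shared arrays.

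The genotype by treatment interaction tests whether the tunicamycin response itself differs between genotypes, as the response in null livers minus that in control livers. Tspyl2 (-2.60 ± 0.22), Zfp9 (-2.77 ± 0.28), Nde1 (-2.74 ± 0.30) and Gmppb (-2.29 ± 0.31) rose less in null livers (largest adjusted p = 0.00793). So did Bhlha15 (-2.84 ± 0.52), the checkpoint kinase gene Chek1 (-2.58 ± 0.39), Ccdc149 (-2.48 ± 0.37) and Mxd1 (-2.35 ± 0.36; largest adjusted p = 0.0286). Without control tunicamycin replicate 2 the calls of Chek1, Ccdc149 and Mxd1 were lost (adjusted p = 0.054, 0.0557 and 0.0564), and that of Bhlha15 was lost without any 1 array except control tunicamycin replicate 3 and null tunicamycin replicate 2 (-2.97 to -2.57, adjusted p = 0.063 to 0.108). Calls were also lost for Bhlha15 with a pseudocount of 1 (-2.76, adjusted p = 0.104) and for Ccdc149 with a pseudocount of 1 (-2.50, adjusted p = 0.0954). In all, 122 genes were called, 120 negative and 2 positive, 113 and 2 of them with at least a 2-fold difference. The positive ones were Bid (1.16 ± 0.19, adjusted p = 0.0199) and Arhgef2 (1.51 ± 0.24, adjusted p = 0.017). Bid lost its call without any 1 of control tunicamycin replicates 1 and 2, null tunicamycin replicate 1, control vehicle replicates 2 and 3 and null vehicle replicate 1 (1.13 to 1.17, adjusted p = 0.0526 to 0.0853), and with the mean of its probe sets (0.69, adjusted p = 0.31) and with the replicate number as a block (1.16, adjusted p = 0.0614). Arhgef2 lost its call without any 1 array except control tunicamycin replicate 3, control vehicle replicates 1 and 2 and null vehicle replicates 2 and 3 (0.52 to 1.56, adjusted p = 0.0527 to 0.523), and with a pseudocount of 1 (0.71, adjusted p = 0.457), with the mean of its probe sets (0.60, adjusted p = 0.376) and without _x_at and _s_at probe sets (0.64, adjusted p = 0.423). Without null tunicamycin replicate 1, 2 or 3 the Arhgef2 value was 0.72, 0.67 or 0.52. Fits without an array picked the brightest probe set anew, so these may have read another Arhgef2 probe set than the main fit. Their values lay near the 0.64 without _x_at and _s_at probe sets, and do not show that single arrays decided the main value. Of the 120 negative genes 118 had risen with tunicamycin in control and 45 in null livers, and 119 were also lower in null livers with tunicamycin, a comparison that shares its arrays. The count changed with the settings and in fits without 1 array. Each such fit has fewer arrays and leaves a group of 2, so a lower count does not by itself single out an array. It was 59 with the replicate number as a block, 225 with array quality weights, and 71 and 186 with pseudocounts of 1 and 64. It was 31, 14 and 107 without control tunicamycin replicate 1, 2 and 3, and 42, 126 and 72 without null tunicamycin replicate 1, 2 and 3. It was 64, 64 and 40 without control vehicle replicate 1, 2 and 3, and 35, 92 and 46 without null vehicle replicate 1, 2 and 3. Of the 126 genes called without null tunicamycin replicate 2, the array with kidney transcripts, 101 were among the 122.

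Genes of ER translocation and export responded less in null livers as a group. The list had a median interaction of -0.85 with 8 of 30 genes called (22 adjusted over the list alone; camera adjusted p = 2.49e-29, adjusted p = 0.0173 with an estimated correlation). Sec24d (-1.29 ± 0.21, adjusted p = 0.0174) lost its call without any 1 of control tunicamycin replicates 1 and 2, null tunicamycin replicate 1, control vehicle replicate 3 and null vehicle replicates 1 and 3 (-1.28 to -1.23, adjusted p = 0.0551 to 0.0765). Srprb (-1.86 ± 0.37, adjusted p = 0.0434) lost its call without any 1 array except null tunicamycin replicate 2 (-2.03 to -1.66, adjusted p = 0.0693 to 0.143), and with a pseudocount of 1 (-1.89, adjusted p = 0.0764), without the filter on dim probe sets (-1.86, adjusted p = 0.053), with the replicate number as a block (-1.86, adjusted p = 0.0775), with the Gapdh ratio as a covariate (-1.88, adjusted p = 0.0545) and with the actin ratio as a covariate (-1.93, adjusted p = 0.0528). Sec61a1 (-1.05 ± 0.20, adjusted p = 0.0339) lost its call without any 1 array except null tunicamycin replicate 2 (-1.12 to -0.96, adjusted p = 0.0553 to 0.129), and with a pseudocount of 1 (-1.06, adjusted p = 0.0603), with the mean of its probe sets (-1.29, adjusted p = 0.0696) and with the replicate number as a block (-1.05, adjusted p = 0.0728). N-glycosylation genes had a median of -0.58 with 3 of 24 called (9 adjusted over the list alone; adjusted p = 1.68e-12, adjusted p = 0.00572 with an estimated correlation), among them Dolpp1 (-1.60 ± 0.25, adjusted p = 0.0164). Dolpp1 lost its call without any 1 of control tunicamycin replicates 1 and 2, null tunicamycin replicate 1 and null vehicle replicate 1 (-1.63 to -1.46, adjusted p = 0.0514 to 0.0592), and with values as deposited (-1.59, adjusted p = 0.0557). ER-associated degradation genes had a median of -0.51 with 2 of 19 called (6 adjusted over the list alone; adjusted p = 3.98e-12, adjusted p = 0.00153 with an estimated correlation), among them Edem2 (-1.58 ± 0.25, adjusted p = 0.017). Edem2 lost its call without any 1 of control tunicamycin replicate 2, null tunicamycin replicate 1 and null vehicle replicate 3 (-1.55 to -1.43, adjusted p = 0.0549 to 0.0567), and with the mean of its probe sets (-0.61, adjusted p = 0.302). These 3 lists kept their calls without each array in turn. ER chaperone genes had a median of -0.23 with 2 of 22 called (3 adjusted over the list alone; adjusted p = 0.0162, adjusted p = 0.439 with an estimated correlation). The chaperone call was lost without either control vehicle replicate 2 or null vehicle replicate 2 (median -0.16 to -0.15, adjusted p = 0.212 to 0.23). Chaperone genes also lost it with the actin ratio as a covariate (median -0.13, adjusted p = 0.108). Among its members Dnajc10 (-1.67 ± 0.27, adjusted p = 0.0177) lost its call without any 1 of control tunicamycin replicates 1 and 2, null tunicamycin replicate 1, control vehicle replicate 3 and null vehicle replicates 1 and 3 (-1.67 to -1.54, adjusted p = 0.0551 to 0.0767), and with the mean of its probe sets (-1.37, adjusted p = 0.0536). Immediate-early genes had a positive median of 0.73 (adjusted p = 0.00113, adjusted p = 0.162 with an estimated correlation; 0 adjusted over the list alone). Fatty acid oxidation genes had one of 0.16 (adjusted p = 0.0447, adjusted p = 0.458 with an estimated correlation; 0 adjusted over the list alone). The fatty acid call was lost without any 1 array except control tunicamycin replicate 3, null tunicamycin replicates 2 and 3, control vehicle replicate 3 and null vehicle replicate 2 (median 0.09 to 0.18, adjusted p = 0.0516 to 0.251). Fatty acid genes also lost it with centred medians (median 0.08, adjusted p = 0.173), with values as deposited (median 0.13, adjusted p = 0.171) and with the Gapdh ratio as a covariate (median 0.16, adjusted p = 0.0586). The ATF4 and CHOP list (-0.19, adjusted p = 0.286) and the genes Hspa5 (0.35 ± 0.27), Ddit3 (-0.64 ± 0.34), Xbp1 (0.66 ± 0.19) and Dnajb9 (-0.43 ± 0.36) did not pass (smallest adjusted p of these genes = 0.216). The other lists did not pass (adjusted p = 0.0674 to 0.945), and median, mean and test differed in sign for the lipid droplet, pericentral and endothelial lists. In fits that kept the call, medians moved more than 1.5-fold for ER chaperone and folding (to -0.15 without control tunicamycin replicate 2, adjusted p = 0.0269 and -0.11 without null tunicamycin replicate 2, adjusted p = 0.0226), fatty acid oxidation (to 0.25 without null tunicamycin replicate 2, adjusted p = 0.00267), and immediate-early (to 0.48 without null tunicamycin replicate 2, adjusted p = 0.000863 and 0.48 without null vehicle replicate 2, adjusted p = 0.0068).

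**Figure D4:**
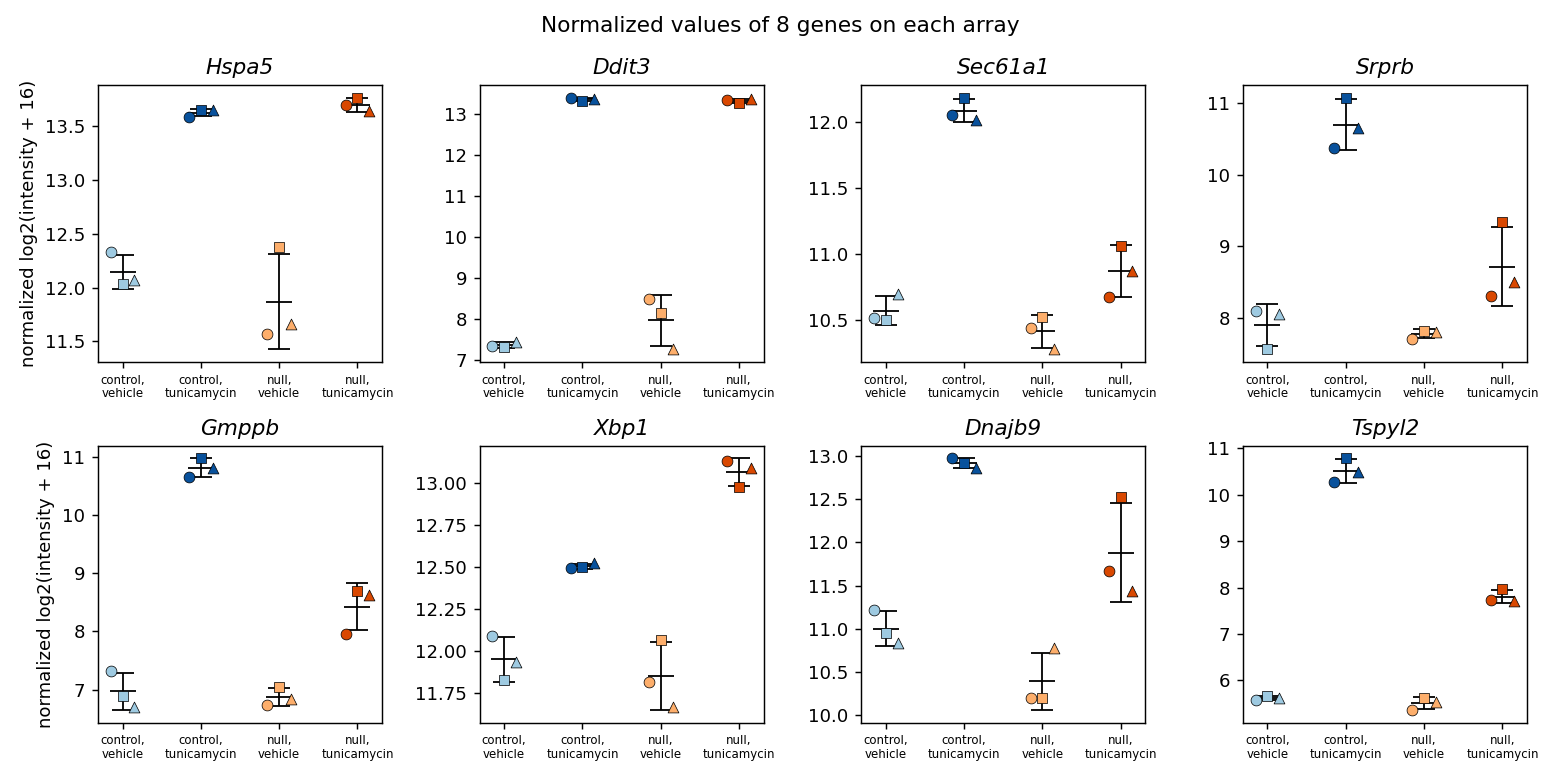
Normalized log2(intensity + 16) of 8 genes on each array, with symbols for replicates and bars for the mean ± SD of 3 arrays. With tunicamycin, Hspa5 and Ddit3 differed between genotypes by 0.07 ± 0.19 and -0.03 ± 0.24, while Srprb, Gmppb and Tspyl2 were lower in null livers (-1.98, -2.38 and -2.72).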

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

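The tests of kidney transcripts, of the smaller translocation response, of single arrays and of the estimated correlation for cholesterol genes were chosen after the results they examine had been seen. So were the Gapdh and actin ratios as covariates, although the bound for cholesterol genes with the Gapdh ratio was written before its value was seen. The counts of other splits were chosen before.

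The response to tunicamycin differed between genotypes by the interaction test. It called 122 genes, and lists differed with medians of -0.85 for ER translocation and export, -0.58 for N-glycosylation, -0.51 for ER-associated degradation, -0.23 for ER chaperones, 0.16 for fatty acid oxidation and 0.73 for immediate-early genes. Of these, the chaperone, fatty acid oxidation and immediate-early lists did not pass with an estimated correlation (adjusted p = 0.439, 0.458 and 0.162). Named genes that differed were Bhlha15 (-2.84), Zfp9 (-2.77), Nde1 (-2.74), Tspyl2 (-2.60), Chek1 (-2.58), Ccdc149 (-2.48), Mxd1 (-2.35), Gmppb (-2.29), Srprb (-1.86), Dnajc10 (-1.67), Dolpp1 (-1.60), Edem2 (-1.58), Sec24d (-1.29), Sec61a1 (-1.05), Bid (1.16) and Arhgef2 (1.51). Of these 16 calls, 12 were lost in at least 1 of the fits without 1 array, and 4 were kept in all of them. Groupings of the arrays that keep the treatment were compared, 100 in all: the real one and others drawn at random. Of these, 8 called at least as many genes as the real one, itself included (real 122, highest other 313). The 8 all keep the real division of the tunicamycin arrays into 2 sets of 3, with the genotype labels in place or swapped. The 10 groupings that do so, the real one included, called 91 to 313, and the other 90 called at most 1. The higher counts thus follow the structure of the tunicamycin arrays, which differ by genotype. By the bound written beforehand, only a share under 0.05 would have argued against chance. The share of 8 in 100 did not meet that bound, so this count does not argue against chance. Since 10 groupings share the division of the tunicamycin arrays with the real one, the share has little power to exclude chance. For the pairwise contrasts 10 splits of 6 arrays are too few for a share under 0.05. With only the 6 arrays fitted, the real and highest other counts were 3679 and 0 for the control response, 1487 and 1 for the null response, 1 and 1 without stress and 364 and 1 with tunicamycin. The numbers of splits as large, the real one included, were 1, 1, 2 and 1.

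Probe sets without a gene symbol, which the gene tests do not use, also responded. Of 5009 tested with limma, 211 were higher and 178 lower after tunicamycin in control livers, and 90 and 133 in null livers. Between genotypes 0 were called without stress and 38 with tunicamycin, and 10 in the interaction.

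Kidney transcripts were raised in null tunicamycin replicate 2. As a hypothesis, mixing of kidney tissue or RNA into this sample is in line with 16 of 21 markers lying more than 1 (log2) above the highest other array, by a median excess of 4.69, while 5 (Slc5a2, Slc22a12, Lrp2, Nphs1 and Wt1) did not. Of the list, 1 marker, Slc5a2, lay above the median gene on the other arrays and 0 are in another list, and abundant markers reached log2 values of 13.1 (Umod), 12.8 (Kap), 12.4 (Fxyd2) and 12.3 (Egf). Dilution of liver transcripts is in line with a median difference of -0.38 (95% bootstrap interval -0.44 to -0.23) from its group mates over 57 complement, lipoprotein and bile acid genes, 51 of them below 0. The bootstrap interval resamples genes and does not measure how far mice differ from one another. Lower RNA integrity is argued against by a log2 Gapdh ratio of -1.32 and a log2 actin ratio of -1.20, both inside the range of the other arrays. No biological explanation was tested, and whether tissue or RNA was mixed, and at which step, stays open.

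Translocation and export genes rose less in null livers (median interaction -0.85, adjusted p = 2.49e-29). A weaker tunicamycin exposure of the null mice that shrank all responses by the same share is argued against by the shares kept. These were 24.8% for translocation and export genes against 92.2% for ATF4 and CHOP targets. The difference was -67.4 percentage points (two-sided permutation p = 2e-05 over genes, smallest possible 1e-05). Genes of a list vary together, so this p does not measure the spread between mice. The lists set against each other had the lowest and highest shares of those compared. A weaker exposure to which the lists respond unequally was not tested and stays open. Both sets hold the members that rose in control livers. Over all members the medians in control and null livers were 0.96 and 0.24 against 2.36 and 2.26. RNA integrity is argued against as the whole cause by a median of -0.84 (adjusted p = 7.84e-29) with the Gapdh ratio as a covariate and -0.89 (adjusted p = 6.53e-27) with the actin ratio, and the array with kidney transcripts by -0.91 (adjusted p = 8.85e-32) without it. A candidate explanation is that full induction of these genes needs Ire1α, a hypothesis drawn from these same arrays and not tested on others. The genotype is confounded with any unlabelled difference between the mice, such as the day of treatment.

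The cholesterol synthesis list had a negative median in null against control livers without stress (-0.58, adjusted p = 1.24e-12, adjusted p = 0.139 with an estimated correlation), and 0 of its genes were called over all genes. RNA integrity as the whole cause is argued against by a median of -0.77 with the Gapdh ratio as a covariate and -0.51 with the actin ratio, and a single deciding array by -0.34 as the value closest to 0 when each vehicle array was left out (without null vehicle replicate 2). Chance variation that these genes share between mice stays open: with an estimated correlation the adjusted p was 0.139, and the real split had the largest median of the 10 splits of 6 arrays (two-sided exact permutation p = 0.1, the smallest that 10 splits give). A biological effect of the deletion also stays open.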

How the results depend on the processing

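Values as deposited and the Gapdh or actin ratio as a covariate were chosen after the data had been seen. The other alternatives were chosen before. Unless stated below, counts stayed within 1.5 times the main count, and the cause of the changes below was not tested where none is given.

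A 2-fold threshold, stricter by construction, gave 1414 genes for the control response (main 3636), 882 for the null response (2449) and 293 between genotypes with tunicamycin (581). The actin ratio as a covariate gave 1885 genes for the control response, and 17 and 20 lists in the control and null responses (main 10 and 12). That ratio was lower in tunicamycin than in vehicle arrays without overlap in control livers, while the null groups overlapped. Testing every probe set, which counts a gene once per probe set, gave 5467 calls for the control response. Fitting only the 2 groups compared, which leaves fewer arrays, gave 1487 for the null response, 364 with tunicamycin and 1 without stress (main 0). Array quality weights gave 1284 with tunicamycin and 225 for the interaction (main 122). The cause was not tested. Pseudocounts of 1 and 64 gave 71 and 186 interaction genes, also without a test of the cause. The replicate number as a block gave 1 gene without stress and 59 interaction genes. Residuals of arrays with the same number correlated at -0.41 to 0.49 and others at -0.45 to 0.37, with 5 of 12 arrays closest to their own number. The highest correlation, 0.49, was between replicate 3 of control vehicle and replicate 3 of control tunicamycin. These values neither show nor exclude that the numbers pair samples.

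Leaving out each array in turn gave 2582 to 4071 genes for the control response, 1614 to 2415 for the null response, 0 in each such fit without stress, 279 to 588 with tunicamycin and 14 to 126 for the interaction. Lists called ranged from 9 to 12, 8 to 15, 7 to 9, 6 to 11 and 4 to 9 in the same order, and the correlation of responses from 0.698 to 0.807 (main 0.774). A group left with 2 arrays is assumed to vary like the others. With an estimated correlation 6, 4, 0, 3 and 3 lists were called in the same order (main 10, 12, 9, 10 and 6), a test that allows for genes of a list varying together.

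Of 130 called values of named genes, 107 kept direction and call in the alternatives run for single genes. Over 4021 alternative values of called and uncalled genes, 3840 kept direction and side of the threshold, 159 lost a call, 1 gained one, 21 uncalled values changed sign and 0 had a call on either side and changed sign. Signal near background may limit dim genes. Without the filter on dim probe sets, 18193 genes were tested and 3458 called in the control response. The main fit tested 14568 and called 3636, and the cause of the difference was not tested.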
